A study of Mus musculus with 6 samples.

How the data were processed

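RNA from 6 mouse macrophage samples was measured by RNA sequencing, 3 of CAR-Ms and 3 of CAR-Trem2-Ms. CAR-Ms are macrophages given a lentivirus so that they carry a chimeric antigen receptor, a synthetic receptor that directs a cell to a chosen surface target. Per the labels, the macrophages grew for 7 days with M-CSF at 20 ng/mL, the growth factor that drives macrophage differentiation, in DMEM, and the tissue is given as skin. The labels of the CAR-Trem2-Ms add a 24 h induction with 1 µM VD3 and a sort by flow cytometry, and mark them as positive in the genotype field where the CAR-Ms are wild type. The treatment protocol shared by all samples also gives VD3, so whether CAR-Ms received it is not settled by the labels. Trem2 status, sorting and, if CAR-Ms did not receive it, VD3 therefore changed together between the groups. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with a SMARTER mRNA-Seq kit.

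The authors deposited one table of 22063 genes with Ensembl identifiers, symbols and KEGG pathways. Per the file headers, it holds raw read counts per gene for each sample, and the count columns are whole numbers whose totals differ between samples. Per the file headers, it also holds TPM values, which the authors scaled for gene length within each library. The deposited log2 fold change was checked against the file and equalled the log2 ratio of the group means of TPM, with a mean of 0 replaced by 0.001. The deposited p-value and its adjusted form are the authors' own, and the tool behind them is not given in the sources used here. Per the submitters' processing notes, fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and the mm10 genome were used; the version of HISAT2, the tool that counted reads and the annotation release are not given in the sources used here. Nothing in the sources says that counting used strand, so reads of overlapping and antisense genes cannot be told apart. Near-identical copies may share reads, which makes the values of Ifi202b, Ifi204, Apol9a, Hspa1b, the haemoglobin genes and ribosomal protein genes uncertain.

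The total count per sample, in units of 1e6, was 14.2, 15.91 and 14.54 in CAR-Ms and 12.56, 9.8 and 12.22 in CAR-Trem2-Ms. No read was listed for 5479 genes. A count of 0 in all samples of a group allows up to 3 counts in the 44.66 (in 1e6) reads of CAR-Ms or the 34.59 (in 1e6) of CAR-Trem2-Ms. Such floors and intervals cover counting error only, since reads copied by PCR are not independent molecules. Replicate pairs were compared with a chi-square statistic over genes with at least 20 reads in the pair. It came to 2.19 to 2.36 per degree of freedom in CAR-Ms and 3.21 to 3.34 in CAR-Trem2-Ms, above the value of 1 that sampling alone gives, so each sample was counted as 1 replicate. No label says that the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

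Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM factors and the filterByExpr filter, which left 11402 genes. P-values were adjusted by the Benjamini-Hochberg method and a gene was called changed at an adjusted p under 0.05. Fold changes are CAR-Trem2-Ms over CAR-Ms, and levels are counts per 1e6 with TMM factors (CPM). The standard error was taken from the fold change and its F statistic. Of 29 gene lists, the 27 with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. KEGG pathways with 10 to 300 tested genes, 324 in all, were tested in each direction with a one-sided hypergeometric test against the 4984 tested genes that carry any pathway. All 10 splits of the 6 samples into 3 and 3 were refitted.

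The groups, the tests, the gene lists, the settings named as planned and the rule for named genes were fixed before the data were examined. The rule names Trem2, Tyrobp and Cyp24a1 with their values in every sample. It adds the 6 largest rises and the 6 largest falls among changed genes with a mean of at least 50 reads in the higher group, no overlap between the groups and a symbol that is not a predicted gene. From each list it takes up to 3 changed members with at least 50 reads and the largest fold change, and, for a list without one, at most 2 of the highest expression, by value only. Of the genes so chosen, 1 is not reported here. The alternatives fixed in advance were RLE and upper quartile factors, no filter and a stricter filter of 10 reads in every sample of a group, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each sample, a log2 fold change of at least 1, an adjusted p under 0.01, an estimated inter-gene correlation, and fry. A planned limma test on FPKM was replaced by limma-trend on log2(TPM + 1) over genes with a TPM of at least 1 in 3 samples, since the table gives TPM. That test was added after seeing the data, like total-count scaling, leaving out mitochondrially encoded genes, a correction for GC content and transcript length alone and with the replicate block, and a smaller limit on the fold change. The correction took out a smooth trend of each library's deviation from the gene mean over GC content and log2 length of the longest transcript in GENCODE release M21. Length and GC content were found for 99.82% of tested genes.

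Coordinates are those of GENCODE M21 on GRCm38, the assembly that mm10 names, and 99.59% of the table's identifiers were found there. Scripts were tested on simulated data drawn from the means and library sizes of this comparison for 11402 genes. With 50 genes planted at each fold, edgeR called 38 at a fold of 1.25, 42 at 1.5, 49 at 2 and 48 at 4, with 10 calls among unchanged genes and 0 calls when nothing was planted. A planted gene list was called by camera, with 0 of the lists that shared no member with it, and a planted pathway ranked 1 among the pathways. The simulated groups were alike apart from the planted genes, so the simulation does not test scaling or calls where most genes change, as here. Genes were drawn independently of each other, so it also does not test camera on lists whose genes vary together. The estimated correlation in the real data was 0.69 for mitochondrially encoded genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.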

Results

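RNA sequencing profiled 6 samples of mouse macrophages engineered with a lentivirus to carry a chimeric antigen receptor. The 3 CAR-Ms samples held the receptor in wild-type cells, and the 3 CAR-Trem2-Ms samples were marked as positive for Trem2, with VD3 at 1 µM for 24 h and a sort by flow cytometry in their own labels. Total counts, in units of 1e6, lay between 14.2 and 15.91 in CAR-Ms and between 9.8 and 12.56 in CAR-Trem2-Ms. The series asks how the transcriptomes of the 2 groups differ, in a study of engineered macrophages and scars. Trem2 status and sorting changed together, and VD3 with them unless CAR-Ms also received it, so each difference below is one between the whole preparations.

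CAR-Trem2-Ms carried more Trem2, which their label implies, and a broad rise of interferon-response and inflammatory genes. Spp1, Lgals3 and Plin2, genes of lipid-associated macrophages, were also higher, in a list where 15 of 22 tested genes rose and 4 fell. Genes of DNA replication, the cholesterol exporters Abca1 and Abcg1, and Vdr, the vitamin D receptor, were lower. Of 11402 tested genes, 9245 (81.1%) changed in edgeR's quasi-likelihood test, 4668 higher and 4577 lower, and 3765 of them by at least 2-fold (2136 higher, 1629 lower). The groups did not overlap in 81.8% of tested genes, where chance gives 10%. The balance of rises and falls depended on scaling. The median log2 fold change over all genes was 0.03 with TMM factors, 0.26 with upper quartile factors (5714 higher, 3606 lower), -0.10 with total-count scaling and -0.63 on log2(TPM + 1) in limma (1890 higher, 6946 lower). Directions below are relative to the TMM scale.

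Trem2, a lipid-sensing surface receptor of macrophages (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147, plus strand, GRCm38), read 78.7, 74.1 and 77.0 CPM in CAR-Ms replicates 1, 2 and 3. In CAR-Trem2-Ms replicates 1, 2 and 3 it read 196.0, 195.1 and 182.5 CPM. The means were 76.6 ± 2.32 and 191.2 ± 7.56 CPM (SD, n = 3 each), a rise of 2.50-fold (log2 1.32 ± 0.04 SE; edgeR, Benjamini-Hochberg adjusted p = 7.8e-21). Counts do not tell the endogenous transcript from an introduced coding sequence. CAR-Trem2-Ms were marked as positive for Trem2, so the rise of Trem2 checks that label and is no independent result. Trem2 also counts as a riser in its own list and in those of lipid-associated macrophages and macrophage identity. Tyrobp, the signalling adaptor of Trem2 (ENSMUSG00000030579, chromosome 7, 30413760 to 30417585, plus strand), read 135.9, 135.0 and 137.4 CPM in CAR-Ms and 229.7, 220.1 and 227.1 CPM in CAR-Trem2-Ms, a rise of 0.73 ± 0.04 (log2, SE). The direction of Tyrobp depended on scaling: its log2 change was -0.025 on log2(TPM + 1), and it fell by 0.17 on the log2 scale after a correction for GC content and transcript length. Of the 16 tested genes in the list of Trem2 and its signalling partners, 6 rose, 6 fell and 4 did not pass. Card9, an adaptor downstream of Syk, rose 5.56-fold from 28.1 ± 0.81 to 156.3 ± 5.40 CPM, while Vav3 and Pik3r1, of the same signalling cascade, fell by 1.85 and 1.70 on the log2 scale. The list's median was -0.07, but 0.16 with upper quartile factors, -0.54 on log2(TPM + 1) with 4 of 15 higher and 9 lower, and -0.21 after the GC and length correction with 4 higher and 8 lower. Its mean was 0.09 and camera, which compares a list with all other genes, gave an upward direction and no call (adjusted p = 0.581).

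**Figure D1:**
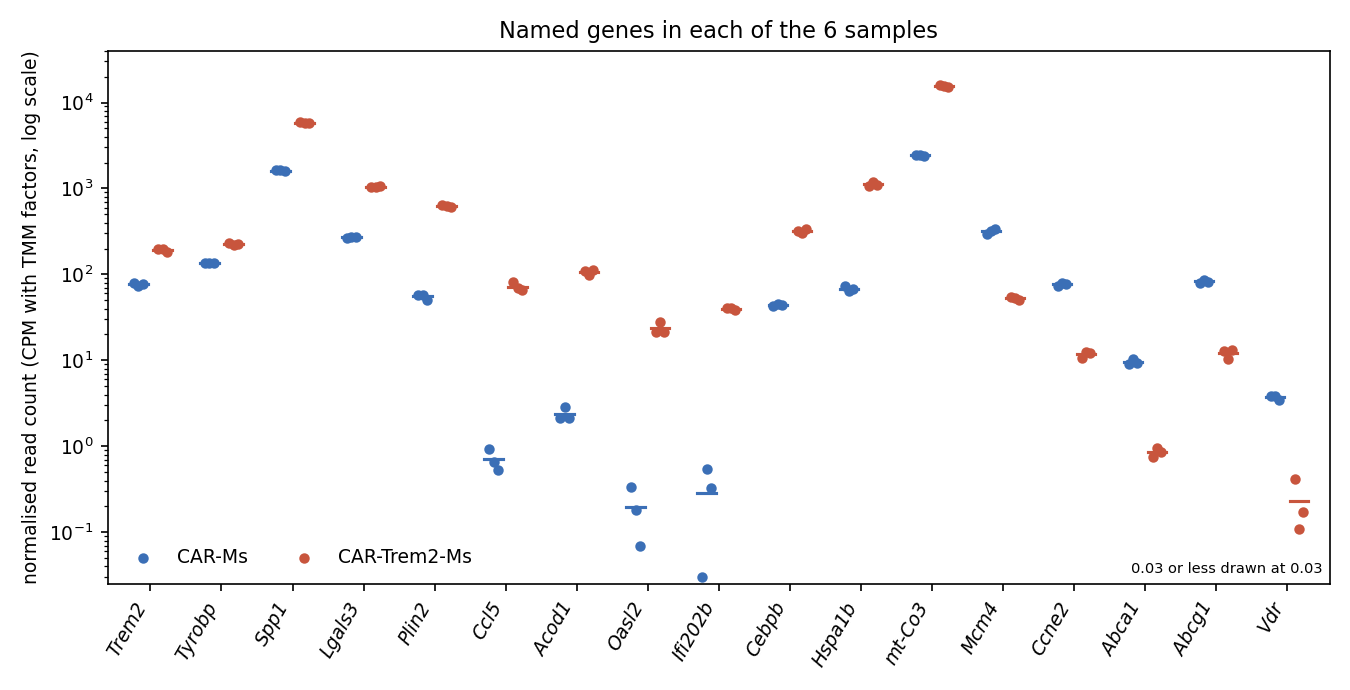
Normalised read counts (CPM with TMM factors, log axis) of 17 named genes, 1 point per sample, blue for CAR-Ms and red for CAR-Trem2-Ms, with a line at each group's mean. Trem2 stood at 76.6 CPM on average in CAR-Ms and 191.2 in CAR-Trem2-Ms, and Vdr at 3.71 and 0.23.

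Interferon-response genes rose together. Of 38 tested genes of the type I interferon list, the antiviral program that cells switch on in response to interferon, 37 rose, 36 of them by at least 2-fold, and 0 fell. Oasl2, an antiviral protein of the oligoadenylate synthetase family, went from 0.19 ± 0.14 to 23.6 ± 3.71 CPM (SD, n = 3 each), Rtp4, an interferon-induced chaperone of receptors, from 0.49 ± 0.11 to 32.8 ± 2.10, and Ifi204, a DNA sensor, from 0.47 ± 0.29 to 22.0 ± 2.17. Isg20, named after its values were seen, was the member that did not pass, at 5.77 ± 0.64 and 4.22 ± 0.80 CPM. The list's median log2 fold change was 3.48, and it was called by camera (adjusted p = 2.6e-15; adjusted p = 0.035 with an estimated correlation). On log2(TPM + 1) the median was 2.09, with 29 of 31 tested members higher. Interferon-induced genes also led the largest rises of all genes: Ifi202b rose by 7.01 ± 0.24 (log2, SE), from 0.29 to 39.8 CPM, and Apol9a by 5.87 ± 0.42, from 0.12 to 8.06 CPM. Sh2d6, which encodes an SH2-domain protein, rose by 6.17 ± 0.13.

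Inflammatory mediators of classically activated macrophages were higher as well, with 20 of 23 tested members risen, 1 fallen and 2 not past the test. Ccl5, a chemokine that attracts T cells and monocytes, rose 101-fold from 0.71 ± 0.21 to 72.3 ± 7.45 CPM, the largest change in this list. Acod1, which makes itaconate, rose 44.7-fold to 107.7 ± 7.67 CPM and Ccl4, a chemokine, 40.0-fold to 224.8 ± 5.19 CPM. The members that did not rise were named after their values were seen: Cd86, a costimulatory receptor, fell by 0.99, and Il1a and Il1b did not pass at 0.87 and 0.82 CPM in CAR-Ms and 0.97 and 0.50 CPM in CAR-Trem2-Ms. The median log2 fold change was 1.65 (camera adjusted p = 2.5e-10; adjusted p = 0.115 with an estimated correlation), and 0.80 on log2(TPM + 1), with 15 of 22 higher and 3 lower.

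Members of the lipid-associated macrophage signature, a program tied to Trem2 in adipose tissue, rose more often than they fell, 15 against 4 of 22 tested, with 3 not past the test. Plin2, the coat protein of lipid droplets, rose 11.2-fold from 55.5 ± 4.05 to 622 ± 21.1 CPM (SD, n = 3 each). Lgals3, a galectin of phagocytes, rose 3.85-fold to 1040.0 ± 13.5 CPM and Spp1, which encodes osteopontin, 3.62-fold from 1616 ± 20.3 to 5850.0 ± 105.9 CPM. Members that did not rise were named after their values were seen. Csf1, Lipa, Fabp5 and Lpl fell by 0.90, 0.74, 0.475 and 0.345 on the log2 scale. Apoe, Itgax and Cst7 did not pass. The list's median was 0.61 (camera adjusted p = 1.5e-07; adjusted p = 0.035 with an estimated correlation), but on log2(TPM + 1) it was -0.29, with 7 members higher and 10 lower, and camera's adjusted p was 0.173. In the list of cholesterol efflux and lipid storage, 12 rose, 11 fell and 3 did not pass. Abca1 and Abcg1, the transporters that carry cholesterol out of macrophages, fell by 3.48 ± 0.27 and 2.77 ± 0.09 on the log2 scale (SE), Abcg1 from 83.2 ± 3.46 to 12.1 ± 1.55 CPM. The list's median was 0.19 (camera adjusted p = 0.772), but -0.62 on log2(TPM + 1), with 6 of 25 higher and 16 lower, and -0.00 after the GC and length correction. In cholesterol biosynthesis, 15 of 24 fell, 6 rose and 3 did not pass. Cyp51 fell by 1.18 while Fdft1 and Mvd, enzymes of the same pathway, rose by 1.51 and 1.29 (median -0.36; camera adjusted p = 0.547). The median was -1.05 on log2(TPM + 1), with 3 higher and 20 lower, and -0.13 with upper quartile factors, with 9 higher and 12 lower.

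Lysosomal genes moved in both directions. Of 46 tested, 24 rose, 16 fell and 6 did not pass, with a median of 0.18 (camera adjusted p = 0.0373; adjusted p = 0.515 with an estimated correlation). The call was also lost with the replicate block (adjusted p = 0.0857 in camera), limma-voom (adjusted p = 0.166) and total-count scaling (adjusted p = 0.119). Grn, which encodes progranulin, rose 5.81-fold from 349.2 ± 5.48 to 2028 ± 49.2 CPM, and Naglu and Atp6v0d2 rose by 1.68 and 1.73 on the log2 scale. The list turned to a median of -0.52 on log2(TPM + 1), where 36 members were lower, and stood at 0.01 after the GC and length correction, with 22 higher and 22 lower. Among 39 genes of phagocytosis and uptake of dead cells, 29 had enough reads to be tested, of which 19 rose, 9 fell and 1 did not pass. Cd300a, an inhibitory receptor for phospholipids, rose 9.29-fold to 137.4 ± 4.95 CPM and Stab1, a scavenger receptor, 5.31-fold to 8.92 ± 0.41 CPM, against the fall of Abca1. The median was 0.61 (camera adjusted p = 0.28), but -0.44 on log2(TPM + 1), with 10 of 26 higher and 15 lower.

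Vitamin D target genes moved in both directions. The treatment protocol shared by all samples also gives VD3, and if CAR-Ms received it, the comparison is no test of VD3. Cyp24a1, the enzyme that breaks down vitamin D and the best known target of its receptor (chromosome 2, 170482708 to 170497145, minus strand), had 8, 2 and 4 reads in CAR-Ms and 0 in each CAR-Trem2-Ms sample. Relative to library totals, without TMM factors, it was at least 3.61-fold lower against a floor of 3 counts over the group. Without CAR-Ms replicate 1, the bound was 2.27-fold, from 6 reads. Its reads were too few to be tested. Vdr fell by 3.90 ± 0.48 on the log2 scale (SE), from 3.71 ± 0.19 to 0.23 ± 0.16 CPM (SD, n = 3 each). Of 17 tested members of the list, 9 rose, 6 fell and 2 did not pass. The largest rises were those of Cebpb, a transcription factor of myeloid cells, which rose 7.31-fold to 319 ± 15.5 CPM, and of Spp1. The median was 0.23 and the mean 0.04 (camera adjusted p = 5.4e-04; adjusted p = 0.18 with an estimated correlation), and the median was -0.45 on log2(TPM + 1), with 6 higher and 11 lower, and -0.28 after the GC and length correction. The call was also lost with limma-voom (camera adjusted p = 0.166) and on log2(TPM + 1) (camera adjusted p = 0.233).

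Genes with a part in scarring moved in both directions. Among 36 profibrotic factors and protease inhibitors, 18 had enough reads to be tested, of which 7 rose, 7 fell and 4 did not pass. Pdgfb, a growth factor for fibroblasts, rose by 2.58 on the log2 scale, from 14.5 ± 1.10 to 87.1 ± 4.04 CPM (SD, n = 3 each), beside Spp1 and Lgals3. On log2(TPM + 1), 4 of 15 rose and 10 fell, with a median of -0.85. With TMM factors the median was -0.36 although the mean was 0.18 and camera's direction was upward (adjusted p = 0.103). Among 38 matrix-degrading enzymes, 21 had enough reads to be tested, of which 11 rose, 4 fell and 6 did not pass. Adam8 rose 1.93-fold to 400.2 ± 12.8 CPM, whereas the sheddases Adam10 and Adam9 fell by 1.83 ± 0.04 and 0.82 ± 0.04 on the log2 scale (SE). This list's median was 0.27 (camera adjusted p = 0.581), but -0.14 on log2(TPM + 1), with 2 of 17 higher and 9 lower.

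Of 20 macrophage identity genes, 17 had enough reads to be tested, of which 14 were higher in CAR-Trem2-Ms and 3 lower. Those left out were Mertk with 0 to 3 reads per sample, Maf with 0 to 4 and Aif1 with 6 to 21. Fcgr1, a high-affinity Fc receptor, rose 3.68-fold to 131.7 ± 3.18 CPM, next to Cebpb. The median was 0.69 (camera adjusted p = 2.1e-04; adjusted p = 0.115 with an estimated correlation). On log2(TPM + 1), 8 members were higher and 7 lower. Of 28 genes of alternative activation, 9 had enough reads to be tested, of which 4 rose and 5 fell. The lectin Clec10a and Stab1 rose by 2.62 and 2.41, and Il1rn, the interleukin 1 receptor antagonist, fell by 1.91; the median was -0.52 with a mean of 0.04 and an upward direction in camera (adjusted p = 0.772). In MHC class II antigen presentation, 6 of 15 rose and 7 fell. Cd74, the invariant chain, rose 3.60-fold from 231.9 ± 3.54 to 834.7 ± 14.2 CPM, while H2-Aa and H2-Ab1 fell from 6.30 ± 2.04 and 3.54 ± 2.09 CPM to 1.36 ± 0.18 and 0.85 ± 0.01. Both chains were highest in CAR-Ms replicate 1, as was Ngp, a neutrophil gene. The list's median was 0.12 and its mean -0.29, with an upward direction in camera (adjusted p = 0.339). The median was -0.56 on log2(TPM + 1), with 1 of 14 higher and 9 lower, -0.42 after the GC and length correction and -0.00 with total-count scaling.

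Cell cycle genes fell. Of 42 tested, 35 fell, 15 of them by at least 2-fold, 5 rose and 2 did not pass. Ccne2, the cyclin that starts DNA synthesis, fell by 2.69 ± 0.09 on the log2 scale (SE), from 76.4 ± 3.30 to 11.9 ± 1.04 CPM (SD, n = 3 each). Mcm4 and Mcm6, subunits of the replicative helicase, fell by 2.59 ± 0.05 and 1.85 ± 0.05. The median was -0.53 (camera adjusted p = 2.5e-06; adjusted p = 0.035 with an estimated correlation), and between -1.22 and -0.30 under the other scalings. In glycolysis, 16 of 24 fell, 6 rose and 2 did not pass. Pfkfb3, an activator of glycolytic flux, fell by 2.27 ± 0.07, while Hk3, a hexokinase of myeloid cells, rose 8.39-fold to 134.5 ± 8.09 CPM and Eno2 3.45-fold to 32.3 ± 5.84 CPM. The median was -0.54 (camera adjusted p = 1.2e-03; adjusted p = 0.18 with an estimated correlation and 0.0682 on log2(TPM + 1), where the median was -1.21).

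Transcripts encoded by the mitochondrial genome took 4.65 ± 0.05% of counts in CAR-Ms and 13.5 ± 0.24% in CAR-Trem2-Ms (SD, n = 3 each). Of these 13 genes, 12 rose, and mt-Nd6, which lies on the opposite strand from the rest, fell by 1.16; it was named after its values were seen. The cytochrome oxidase subunit mt-Co3 rose 6.43-fold, and mt-Atp8 and mt-Atp6, ATP synthase subunits that overlap on the genome, rose 5.45-fold and 5.36-fold. The median was 1.49 (camera adjusted p = 2.1e-24; adjusted p = 0.115 with an estimated correlation). It was 0.57 on log2(TPM + 1), with 9 higher and 4 lower, and 0.96 after the GC and length correction, with 11 higher and 2 lower. Nuclear genes of oxidative phosphorylation split into 24 that rose, 20 that fell and 5 not past the test, with a median of 0.04 (camera adjusted p = 0.971), which was -0.09 with total-count scaling and -0.56 on log2(TPM + 1), where 5 were higher and 43 lower. Uqcrq, Ndufa2 and Ndufa6 rose by 1.49, 1.39 and 1.23. After the correction for GC content and length the list had a median of -0.39, with 8 higher and 35 lower, and was called lower.

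Stress genes were mixed. Of 31 immediate early and heat shock genes, 19 rose, 10 fell and 2 did not pass, with a median of 0.50 (camera adjusted p = 0.0612). Camera called the list upward with upper quartile factors (adjusted p = 0.0172), with no filter on low counts (0.0286) and without CAR-Trem2-Ms replicate 1 (0.0444) or replicate 2 (0.0364), while its median was -0.29 on log2(TPM + 1), with 12 higher and 16 lower. The heat shock chaperone Hspa1b rose 16.5-fold from 68.3 ± 4.35 to 1125 ± 55.2 CPM, and the transcription factors Myc and Klf2 rose 7.25-fold and 7.09-fold. In the unfolded protein and integrated stress response, 13 of 28 rose and 15 fell. Slc7a11, the cystine importer, fell by 2.26, and Cth and Chac1, enzymes of cysteine and glutathione turnover, rose by 2.25 and 2.10; the median was -0.31, the mean 0.08, camera's direction downward and its adjusted p = 0.961. On log2(TPM + 1) the median was -0.99, with 7 higher and 19 lower.

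**Figure D2:**
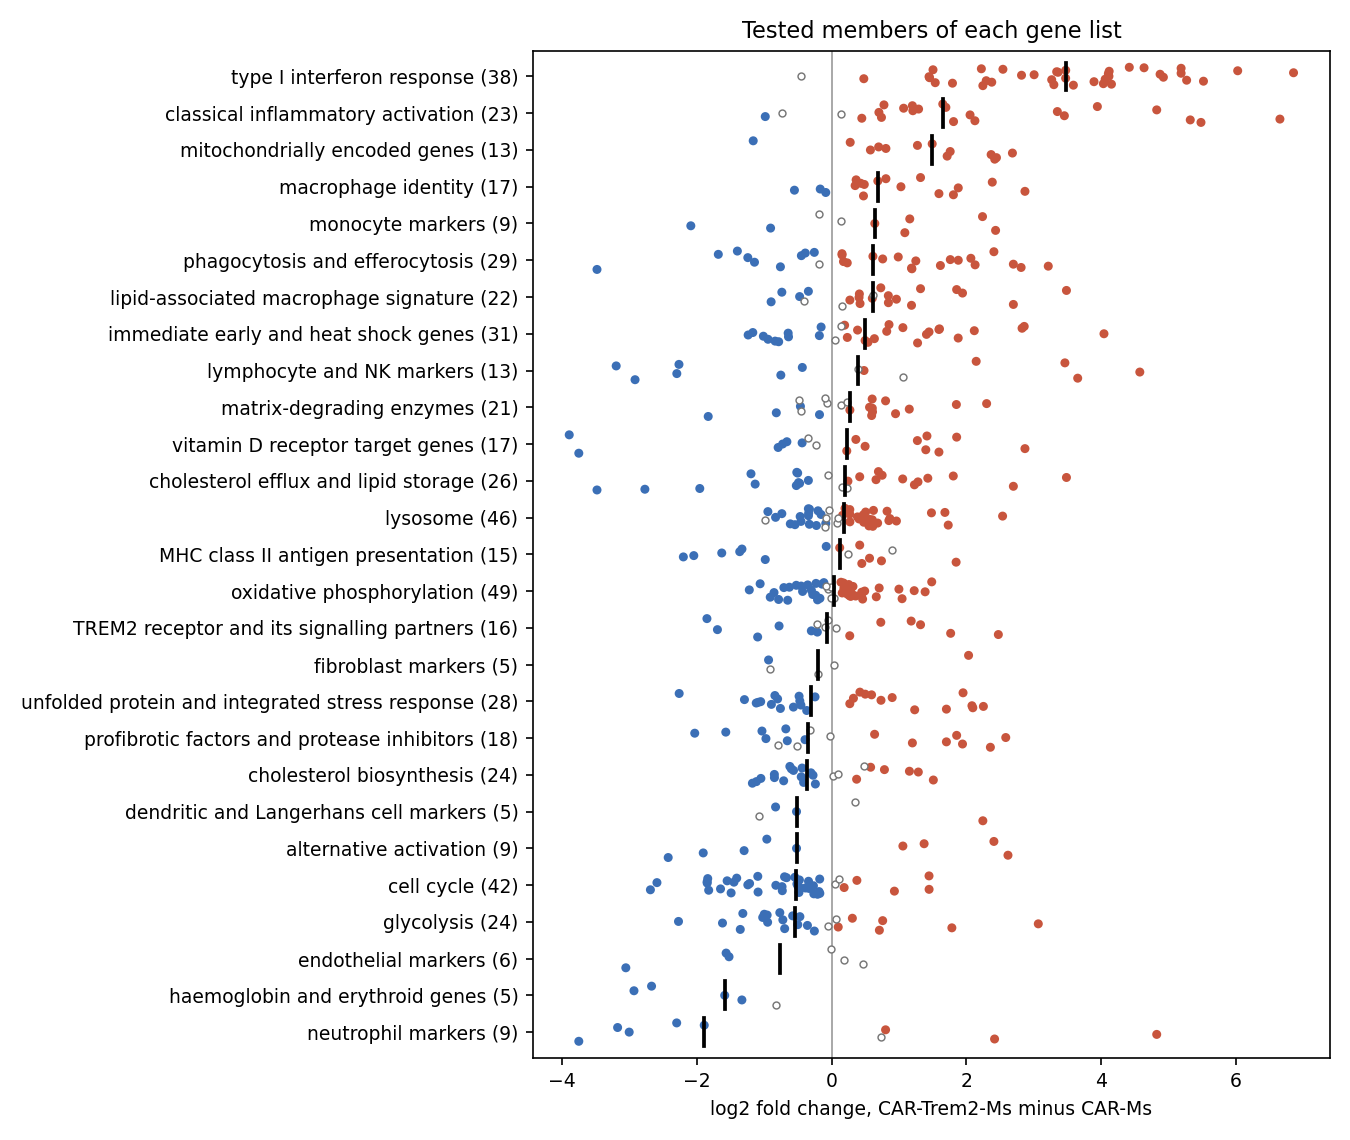
Log2 fold change (CAR-Trem2-Ms minus CAR-Ms) of each tested member of 27 gene lists, with the number of tested members in brackets and a black bar at the median. Filled points passed an adjusted p under 0.05 in edgeR, red higher and blue lower, and open points did not; type I interferon genes stand at a median of 3.48 and cell cycle genes at -0.53.

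Markers of other cells ranged from under 1 CPM to over 100 CPM. Among monocyte markers, 5 of 9 rose and 2 fell, with Clec4e and Spn, both also made by macrophages, up 5.40-fold and 4.72-fold and Ccr2 up 2.12-fold, a call lost on log2(TPM + 1) at 0.32 (median 0.64; camera adjusted p = 0.339). On log2(TPM + 1), 3 of the monocyte markers were higher and 3 lower. Of 9 tested neutrophil markers, 3 rose and 5 fell. Lcn2, which activated macrophages also make, rose 28.4-fold to 109.3 ± 3.75 CPM, while the granule genes Ngp and Ltf fell from 7.47 ± 2.94 and 4.73 ± 2.32 to 0.82 ± 0.12 and 0.60 ± 0.32 CPM (SD, n = 3 each). The list's median was -1.89 and its mean -0.59 although camera's direction was upward (adjusted p = 0.669). Of 5 tested haemoglobin and erythroid genes, 4 fell and 0 rose, with Hbb-bs at 4.29 ± 3.07 and 0.66 ± 0.09 CPM (median -1.59; camera adjusted p = 0.772). Of 13 lymphocyte and NK genes, 5 rose, 6 fell and 2 did not pass. Ighm, whose direction turned on log2(TPM + 1) at -0.22, read 81.2 ± 10.4 and 113.3 ± 2.17 CPM, Lck 20.8 ± 1.96 and 15.5 ± 2.81, and Cd79a 4.03 ± 1.02 and 2.40 ± 0.69 (list median 0.39; camera adjusted p = 0.928; median -0.63 on log2(TPM + 1)). The fall of Cd79a was lost without CAR-Ms replicate 1, CAR-Ms replicate 3 or CAR-Trem2-Ms replicate 3, where its change was -0.57, -0.76 and -0.56, and with upper quartile factors (-0.52). The fall of Lck was lost with upper quartile factors (-0.20), and the rise of Ighm after the GC and length correction (0.09).

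Of 5 dendritic and Langerhans cell genes, 1 rose and 2 fell. Bst2, itself interferon-induced, rose 4.74-fold, Tcf4 fell by 0.83, and Irf4 fell by 0.52, a call lost without CAR-Ms replicate 3 (-0.45), with upper quartile factors (-0.29) and after the GC and length correction (-0.23); the list's median was -0.52, its mean 0.03, its direction upward and its camera adjusted p = 0.772. Fibroblast markers were nearly absent, with 5 of 27 tested, 1 up and 1 down. Tagln read 3.65 ± 0.68 and 1.89 ± 0.59 CPM, and its fall was lost without CAR-Ms replicate 3, at -0.83 (list median -0.20, mean 0.00, camera adjusted p = 0.971). With upper quartile factors the fibroblast median was 0.03, and it was 0.15 after the GC and length correction. The keratinocyte gene Sfn, the one of 22 that could be tested, read 0.92 ± 0.11 and 2.79 ± 1.54 CPM. Of 6 endothelial genes, 3 fell and 0 rose, and the most expressed, Egfl7 and Eng, read 2.33 ± 0.92 and 2.198 ± 0.51 CPM in CAR-Ms and 3.27 ± 1.13 and 2.52 ± 1.13 CPM in CAR-Trem2-Ms (list median -0.77; camera adjusted p = 0.928). Of 3 mast cell and basophil genes, Hdc rose 6.20-fold to 7.16 ± 2.97 CPM and Il1rl1 fell by 0.81.

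The 6 largest falls were spread over genes with no list in common. Myo15a, an unconventional myosin, fell by 4.46 ± 0.19 on the log2 scale (SE), from 28.7 ± 3.22 to 1.29 ± 0.34 CPM (SD, n = 3 each). Npc1l1, the sterol transporter of the intestine, fell from 16.9 ± 1.13 to 0.76 ± 0.44 CPM and Tmem236 from 17.7 ± 1.41 to 0.89 ± 0.52. The potassium channel gene Kcnj14 fell by 4.48 ± 0.45 and the lipid flippase Atp8a2 by 4.69 ± 0.58. Klhl30 had 183 reads over the CAR-Ms samples and 1 over the CAR-Trem2-Ms samples. Relative to library totals, without TMM factors, it was 142-fold lower with a 95% counting interval of 25.1 to 5628 (exact binomial).

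In all, 9 of 27 lists were called, 7 upward and 2 downward. Adjusted over the list alone, the counts above were the same apart from 6 rises in cell cycle, 17 falls in glycolysis and 5 falls among haemoglobin genes. With an estimated correlation the interferon, lipid-associated macrophage and cell cycle lists held. In the other splits of the samples, camera called 4 to 6 lists at the preset correlation and 0 with an estimated one. Of KEGG pathways, 33 were enriched, 15 among higher and 18 among lower genes. The COVID-19 pathway, which holds ribosomal protein genes together with interferon genes, had the smallest adjusted p, with 140 of 184 genes higher (Benjamini-Hochberg adjusted p = 3.9e-21), followed by Ribosome with 105 of 134 (adjusted p = 2.2e-17). Of the 4984 background genes, 40.15% were higher and 42.05% lower. Systemic lupus erythematosus (49 of 73) and Neutrophil extracellular trap formation (78 of 131) also held more higher genes (hypergeometric adjusted p = 3.2e-04 and 4.8e-04). NOD-like receptor signaling had 75 of 141 genes higher (53.19%; adjusted p = 0.0252). Against the rise of Ribosome, Ribosome biogenesis in eukaryotes had 48 of 71 genes lower (hypergeometric adjusted p = 9.9e-04). Among lower genes were Cell cycle (75 of 117; adjusted p = 1.6e-04), DNA replication (28 of 36; adjusted p = 1.1e-03), Nucleocytoplasmic transport (71 of 103; adjusted p = 5.2e-06) and TGF-beta signaling (34 of 52; adjusted p = 0.0178). Oxidative phosphorylation (68 of 119 higher; adjusted p = 5.9e-03), Toll-like receptor signaling (44 of 77 higher; adjusted p = 0.0371), Steroid biosynthesis (14 of 18 lower; adjusted p = 0.0455) and TGF-beta signaling were no longer enriched after the correction for GC content and length, where 13 of the 33 pathways were.

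Fold changes followed the length and GC content of transcripts. Across the 11382 tested genes with an annotated transcript, which are not independent replicates, Spearman's rho of log2 fold change was -0.306 with length and 0.282 with GC content. Ribosomal protein genes, which are short, took 4.29 ± 0.07% of counts in CAR-Ms and 9.06 ± 0.06% in CAR-Trem2-Ms (SD, n = 3 each). The authors' deposited table lists 9360 genes at an adjusted p under 0.05, 3047 positive and 6311 negative. Of 8962 genes called in both, 1598 had opposite signs. The median log2 fold change of tested genes was -0.68 in the authors' deposited table. Trem2 was listed there at 0.61 and Tyrobp at -0.025.

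**Figure D3:**
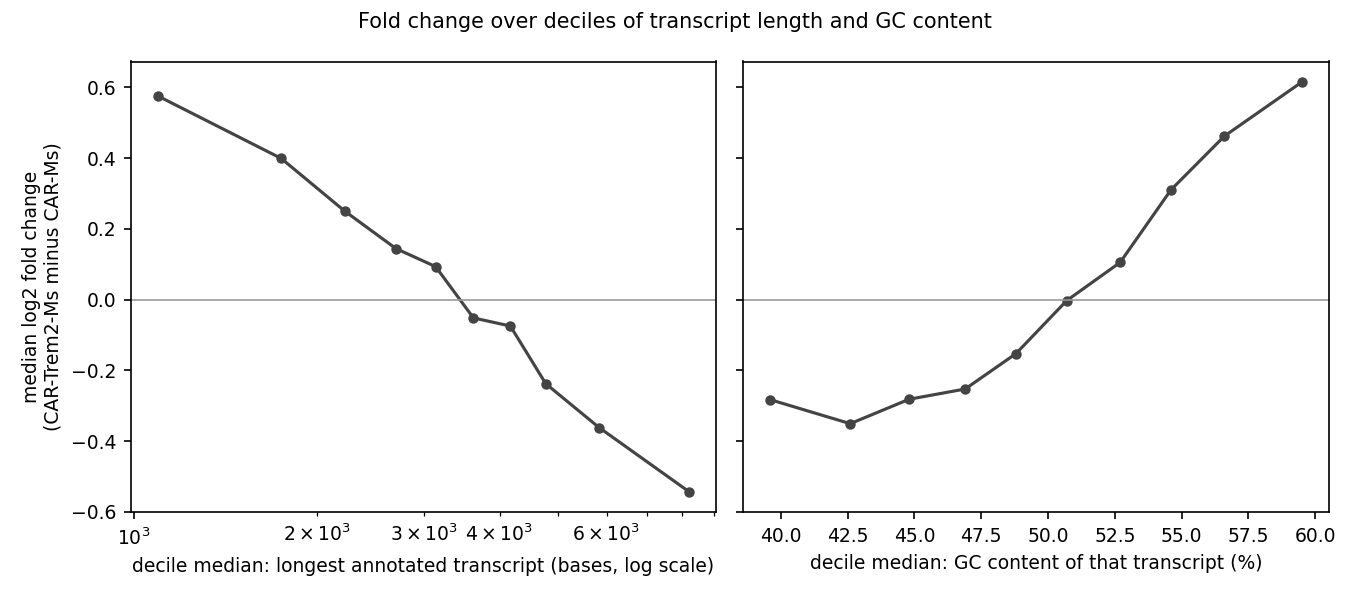
Median log2 fold change (CAR-Trem2-Ms minus CAR-Ms, vertical axis) in each of 10 equal bins of the tested genes by transcript length in bases (left, log axis) and by GC content in percent (right). The median went from 0.58 in the bin of the shortest transcripts to -0.54 in that of the longest, and from -0.28 in the bin with the least GC to 0.61 in that with the most.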

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

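Limma-trend on log2(TPM + 1), total-count scaling, leaving out mitochondrially encoded genes, the GC and length correction with and without the replicate block, and a smaller fold limit were chosen after seeing the data; the planned test on FPKM was not run, since the table holds none. Of 101 counts under the alternatives, 87 lay within 1.5 times the reported one. Of 534 values of gene lists, 495 either kept the call and its direction or were uncalled under both settings, whatever their direction. A further 17 lost the call, 19 gained it and in 3 the test's direction reversed with a call under 1 of the settings compared. The list medians, read apart from the test, changed sign in 44. Among them were 10 of 24 on log2(TPM + 1) and 5 of 27 with the GC and length correction. Of 1490 values of named genes, 1470 were the same by this rule, 16 lost the call and 4 reversed.

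With a log2 fold change of at least 1, 3765 genes changed, 2136 higher and 1629 lower, and 2972 were lower at the smaller limit, as a stricter limit entails. On log2(TPM + 1), 1890 genes were higher and 6946 lower, 5 lists were called, and the test's direction for lysosome and the changes of Tyrobp and Ighm reversed, at -0.524 (median), -0.025 and -0.216. The GC and length correction reversed the test's direction for oxidative phosphorylation, at a median of -0.386, and Tyrobp, at -0.167, while the medians of vitamin D targets and MHC class II turned to -0.28 and -0.42. With the replicate block added to it, oxidative phosphorylation and Tyrobp stood at -0.387 and -0.167. Enriched KEGG pathways numbered 90 with no filter on low counts, 83 with DESeq2, 18 with total-count scaling, 16 with the GC and length correction and 17 with the replicate block added. Camera called 3 lists with an estimated correlation and fry, which does not compare a list with other genes, 24. For pathways and reversals the cause was not tested within these settings. Opposite signs between the deposited TPM comparison and the count fit, Tyrobp among them, are examined below.

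Without 1 replicate at a time, 8911 to 9237 genes changed, 4497 to 4662 higher and 4414 to 4575 lower, with 8 to 10 lists and 31 to 39 pathways. The lysosome call was lost without CAR-Ms replicate 1 or 2, where its median was 0.17. With the replicate block, 9188 genes changed (4627 higher, 4561 lower), with 8 lists, lysosome being the one lost, and 34 pathways. The residuals of samples with the same number correlated at 0.02, 0.002 and 0.005 over 7884 genes. They gave no sign of pairing by number, which does not show that such samples shared no culture or day. Depth limits genes such as Cyp24a1, where 0 reads in CAR-Trem2-Ms allow up to 3 counts over the group.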

Other observations

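Within the cell cycle list, where 35 of 42 members fell, some genes are given here that were chosen after their values were seen. Mcm3, a helicase subunit, fell by 1.85, Rrm1, a subunit of ribonucleotide reductase, by 1.84 and Ccne1 by 1.82 on the log2 scale. The 5 members that rose were Cdc20 (1.45), Ube2c (1.45), Ccnb2 (0.93), Nusap1 (0.38) and Cenpa (0.19), and Plk1 and Kif20a did not pass. Mki67, the proliferation marker, fell by 1.55, from 959.3 ± 6.57 to 327.3 ± 9.36 CPM (SD, n = 3 each).

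Metallothionein genes, which bind zinc and copper, rose, and were also chosen after their values were seen. Mt2 rose by 2.22, from 412.6 ± 11.9 to 1917 ± 79.7 CPM, and Mt1 by 1.36, from 295.3 ± 5.34 to 756.7 ± 12.5 CPM. Mrc1, a marker of alternative activation, had 8, 0 and 4 reads in CAR-Ms and 0, 5 and 2 in CAR-Trem2-Ms. Tgfbr1 and Tgfbr2, the receptors of TGF-beta, and Tgfb1, a ligand, were not chosen by the rule for named genes. The receptors fell by 1.57 and 1.03, while Tgfb1 rose by 0.64.

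The tests of length and GC content on the interferon and cell cycle lists, the splits for genes changed and the blood and marrow list were chosen after the result was seen. Interferon genes rose while cell cycle genes fell. Length or GC bias as the whole cause is argued against by medians of 3.678 for interferon genes and -0.638 for cell cycle genes after the correction. Scaling stays open for the fall in absolute amount, since counts give amounts relative to other genes. Trem2, sorting and VD3, if CAR-Ms did not receive it, stay open together, untested. The real split gave 9245 changed genes in edgeR and the highest other 0 (9 to 21 at an unadjusted p under 0.05), and 33 pathways against 0. Camera at the preset correlation called 9 lists in the real split and 4 to 6 in the others. With an estimated correlation it called 3 and 0. Every other split mixes both groups on each side, so the difference between the groups enters the spread within each side. The low counts of genes and pathways there follow from this and do not measure chance. The sides also hold unequal numbers of each group, so part of the group difference stays. The lists called there therefore do not measure chance either, and a call at the preset correlation alone is weak evidence. In each, 1 of 10 splits reached the real value, and 10 splits are too few for a share under 0.05.

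The deposited comparison and the fit to counts differed in sign for 1598 genes, among them Tyrobp. The deposited log2 fold changes minus the fitted ones had a median of -0.692 and an interquartile range of 0.068, close to 1 shift common to all genes from the TPM denominators. Since TPM scales each gene by its length within each library, a nearly common shift was largely built in. The narrow range describes the shift and is no test of its source. Mitochondrially encoded genes took 12.96% of TPM in CAR-Ms and 28.2% in CAR-Trem2-Ms; without them the median log2 ratio of TPM was still -0.404, which argues against these genes as the whole cause, and without ribosomal protein genes as well (15.2% and 22.5% of TPM) it was -0.149. Without these genes, log2 fold change still fell with transcript length (Spearman's rho -0.297 across genes, which are not independent replicates). A length-dependent yield of the libraries cannot be told apart from a biological difference, since the length slopes of the libraries split by group.

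Some libraries held transcripts of other tissues, in marker lists written after Myh6, Actc1, Mb, Alb and marrow genes had been seen. In CAR-Ms replicate 1, 8 of 30 heart genes had at least 5 reads and over 3 times the CPM of any other library, which leaves heart RNA open. Myh6 had 201 reads there and 5, 2, 0, 0 and 0 elsewhere. By reads alone, the rule used for liver, 25 of 30 heart genes had at least 5 reads there, against 8 to 13 in the other libraries. Of the heart genes, 5 had 10 reads in every library. Liver RNA in CAR-Ms replicate 3 is a candidate source of 22 of 30 liver genes with at least 5 reads, with Alb at 133 reads there. However, CAR-Ms replicate 2 and CAR-Trem2-Ms replicate 3 had 19 and 16 such genes, with Alb at 72 and 104 reads. By the rule used for heart, 3 liver genes passed in CAR-Ms replicate 3, so the results of the unlike rules cannot be compared. Of 27 blood and marrow genes with 10 reads in all, 11 (40.74%) had over 3 times the mean CPM in CAR-Ms. Ngp had 158, 114 and 74 reads against 11, 8 and 8. The T cell genes Cd3e, Cd3g and Trbc2 of the blood and marrow list went the other way, with Cd3g at 1, 4 and 3 reads in CAR-Ms against 14, 22 and 6. Of the 39 genes of that list, 22 are also in the lists of the report. RNA of blood cells cannot be told apart from a group difference, and the sort of CAR-Trem2-Ms could have removed such cells. Skeletal muscle genes with at least 5 reads numbered 3 to 5 of 12 in every library.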
